A study of Mus musculus with 2 samples.

How the data were processed

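Total RNA from cultured mouse intestinal stem cells was sequenced as single-end 50-base reads on a BGISEQ-500 instrument, at 59000000 reads per sample on average, per the labels' protocols. The series holds 2 libraries, 1 labelled wild type (WT) and 1 labelled Stat6 knockout (KO). The labels' protocols describe a lentivirus carrying CRISPR/Cas and Stat6 guide RNAs followed by screening for deficient cells. That protocol text stands unchanged under both samples, so whether the WT culture received a control virus is not given in the sources used here. Genotype was taken from the genotype label of each sample.

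The deposited values were FPKM (fragments per kilobase of transcript, scaled to the library's mapped reads) per gene, per the file headers, rounded to 2 decimals. Per the submitters' processing notes, HISAT, Bowtie2, RSEM and the mm9 genome build were used. Their versions and roles, the gene annotation and any filter on genes are not given in the sources used here. FPKM divides by a library total, so a few very abundant genes that differ between libraries move all other values. Reads from near-identical genes are divided among the copies by estimation, so values of single members of multigene families are uncertain. Both tables listed the same 18944 genes by Entrez gene number and symbol. Spreadsheet conversion had turned 27 of the symbols into dates, and Entrez numbers were used to keep these rows apart. No coordinates are given, because the annotation used here was of a later build than mm9.

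Depth was estimated from the smallest steps of the FPKM values, since the tables hold no counts. Among 91 short RNA genes above 0 in both libraries, 50 had a KO to WT ratio within 2% of a step-size ratio multiplied by a ratio of whole numbers up to 3. That is 54.9%, where 6.28% would be expected of evenly spread ratios. The step-size ratio was chosen to make this count high, which the 6.28% does not allow for. The relative depth of KO to WT was 1.02. With gene lengths from a RefSeq table, which held 18897 of the Entrez numbers, the steps corresponded to 20100000 reads in WT and 20500000 reads in KO. The effective length was the annotated length minus 37 bases. Only depths below the labels' average were searched, so an estimate below that average was fixed in advance. In WT, 87.3% of the values of up to 5 reads lay within 0.1 read of a whole number, and in KO 88.8% did. The depth and the 37 bases were chosen to bring such values closest to whole reads, so these shares are no separate check.

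The measure of difference was log2((KO FPKM + 1)/(WT FPKM + 1)), called the log2 ratio, over genes at 1 FPKM or more in at least 1 library. The pseudocount of 1 understates the fold change of low genes. A gene was counted as higher or lower in KO when its log2 ratio was at least 1 in size, which is 2-fold. With 1 library per genotype no test of genotype, standard error or p-value was computed. The 1 bootstrap interval given in the closing section runs over genes, which are not replicates. Tests that need counts were not used.

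The gene lists, the named-genes rule, the threshold and most alternative settings were all fixed before the data were examined. There were 42 gene lists covering stem cells, epithelial lineages, signalling, stress, metabolism and other cell types. For each list the median log2 ratio over measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called high in KO at a percentile of 97.5 or more and low at 2.5 or less. Lists with fewer than 5 measured members received no percentile. Such percentiles describe these 2 libraries and do not test genotype.

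The named genes were Stat6, Foxp1, Ctnnb1, Il4ra, Il13ra1 and Lgr5, then the 12 highest and the 12 lowest log2 ratios, leaving out predicted models, clone names, pseudogenes and the red blood cell and sex lists. Each list described adds up to 4 members. These were the 2 highest and the 2 lowest, or the 4 largest in size where members past 2-fold all lay on 1 side. Some genes that this rule selects are not reported here.

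The alternative settings were pseudocounts of 0.1 and 5, a trimmed mean of log ratios (TMM) factor with trims of 30% and 5%, the median log2 ratio set to 0, and a total without ribosomal protein genes, mitochondrial genes and the 20 most abundant genes. Others were 3 other minimum levels, thresholds of 1.5-fold and 4-fold, list means, and list members that no other list holds.

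The calculations were tested on simulated data with 17349 genes at the estimated depths, of which 200 were changed. For this WT against KO comparison, 50 of 50 genes raised 3-fold and 50 of 50 raised 4-fold were called. Of genes lowered 3-fold, 46 of 50 were called, and of those lowered 4-fold, 49 of 50. The changed genes were drawn only from those at a mean of 2 FPKM or more, and only counting noise was simulated. At such levels these folds mostly stay past 2-fold despite the pseudocount, so the high shares were largely fixed in advance. They do not cover lower genes or the spread between cultures. Among 200 unchanged simulated lists of 20 genes, 8 were called. A second simulation covered only genes with a length, and no gene differed. Counting noise alone then put on average 6.65 genes past 2-fold over 20 draws. Gene lengths and GC content for these steps came from GENCODE M21, which gave a value for 95.6% of the measured genes. How many short non-coding RNAs the simulation held was not recorded, and some of these rest on few reads. Of 164 measured snoRNAs and microRNA hairpins, 38 were at least 2-fold higher and 65 lower in the real libraries. The 6.65 is therefore no noise level for all the genes counted. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.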

Results

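Gene expression was measured by RNA sequencing in cultures labelled as mouse intestinal stem cells, the Lgr5-marked crypt cells that renew the gut lining. Lgr5 was at 1.79 FPKM in WT and 1.88 FPKM in KO, and the enterocyte gene Fabp1 at 2173 and 7580 FPKM. Transcripts of differentiated cells were therefore abundant in both cultures. The cells carried Lgr5GFP-CreERT2, an allele that places a green fluorescent protein and an inducible Cre recombinase under the control of Lgr5, and came from mice aged 2 months. There was 1 WT library and 1 Stat6 KO library. STAT6 is the transcription factor that the cytokines IL-4 and IL-13 activate, and the comparison asks how the transcriptome of these cells differs without it. With 1 library per genotype, no difference reported here has a replicate check. The FPKM values summed to 504214 in WT and 496255 in KO, and 12079 of 18944 genes reached 1 FPKM in at least 1 library. The estimated depths were 20100000 reads in WT and 20500000 reads in KO, so that 1 FPKM in a transcript of 2 kilobases stands for about 40.6 reads.

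The Stat6 transcript (Entrez gene 20852) was at 41.3 FPKM in WT and 44.2 FPKM in KO, a log2 ratio of 0.10. A small insertion or deletion made by CRISPR need not lower a transcript, so this level does not check the genotype label, which rests on the labels alone. Genes of absorptive enterocytes, the nutrient-absorbing cells of the villus, stood far higher in the KO library, with 19 of 26 measured members at least 2-fold higher. The medians of the lists for hormone-producing enteroendocrine cells, the cell cycle, NF-kB signalling and fetal-like epithelium were called low, although most members stayed within 2-fold, with 5 of 20, 2 of 30, 6 of 17 and 2 of 20 at least 2-fold lower. Paneth, goblet and tuft cell lists were not called in either direction.

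In total 295 genes were at least 2-fold higher in KO and 263 at least 2-fold lower, out of 12079. The median log2 ratio of all measured genes was -0.18, so most genes read slightly lower in KO, and list medians are also given relative to it. With a TMM factor that median became 0.02, and the split changed from 52.9% higher and 47.1% lower to 71.9% higher and 28.1% lower, with 437 and 171 genes. With a pseudocount of 0.1 the majority turned over, to 38.2% higher and 61.8% lower, with 374 and 604 genes.

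**Figure D1:**
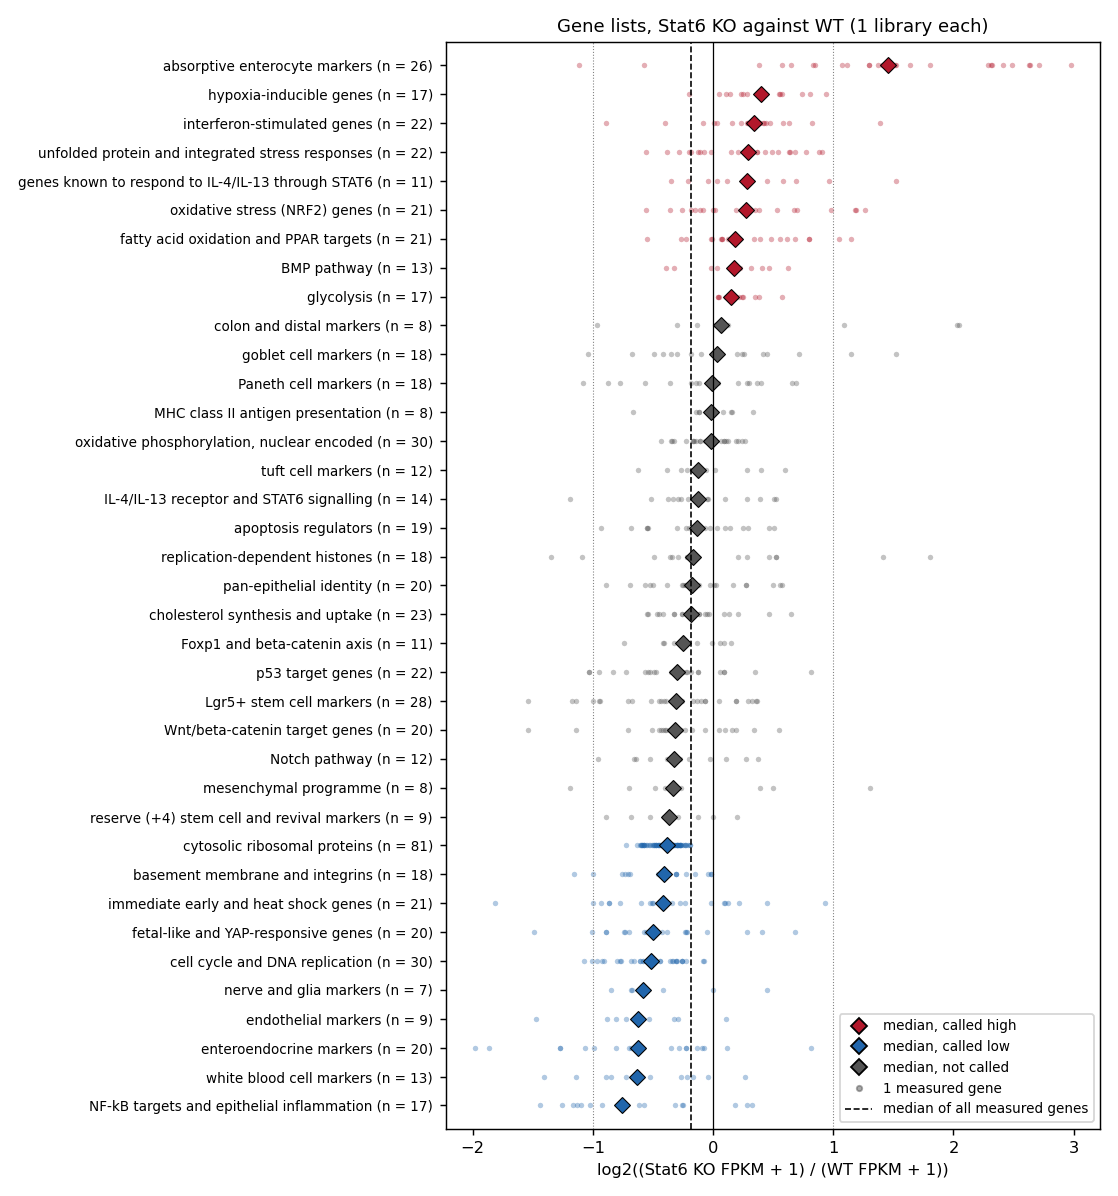
Log2 ratio of Stat6 KO to WT (horizontal axis, FPKM plus 1) for the measured members of each gene list (vertical axis), with 1 small point per gene and a diamond at the list median. The absorptive enterocyte median lies at 1.46, the highest of the lists, and the NF-kB median at -0.76, the lowest, while the dashed line marks the median of all measured genes at -0.18.

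The absorptive enterocyte list had a median log2 ratio of 1.46, which was 1.64 above the median of all genes and higher than all 10000 matched random lists. Lct, the brush-border lactase, was at 0.53 FPKM in WT and 11.03 FPKM in KO (log2 ratio 2.98). Apoa1, a major apolipoprotein of secreted lipoprotein particles, went from 130.3 to 859.7 FPKM (2.71). The list also held members on the other side. Reg3g, a secreted antibacterial lectin, was lower in KO (358 against 165 FPKM, log2 ratio -1.12), and the related Reg3b had a log2 ratio of -0.58.

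The highest log2 ratio belonged to Defa-rs7, an alpha-defensin-related gene with close copies, which was listed at 0 in WT and at 47.4 FPKM in KO. Next came Maob, a mitochondrial amine oxidase, at 2.44 and 32.3 FPKM (3.27). Several others of the 12 highest were enzymes of the brush border and of drug metabolism. The membrane peptidases Mme (neprilysin), Enpep (glutamyl aminopeptidase) and Ace had log2 ratios of 2.99, 2.63 and 2.63. Enpep was at 31.2 FPKM in WT and 198.8 FPKM in KO. The cytochrome P450 genes Cyp2c29 (3.26) and Cyp2b10 (2.75) and the glucuronosyltransferase Ugt2b5 (2.77) belong to multigene families, so their single values are uncertain. Scin, an actin-severing protein, was at 5 and 46.3 FPKM (2.98).

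The lowest log2 ratios belonged to genes of other kinds. The proliferin genes Prl2c3 (-3.76), Prl2c2 (-3.58) and Prl2c5 (-2.65), which encode prolactin-family hormones, are near-identical copies and are uncertain 1 by 1. Tppp and Tppp3, which promote tubulin polymerization, were at 18.3 and 57.4 FPKM in WT and at 0.98 and 5.46 FPKM in KO, with log2 ratios of -3.28 and -3.18. Edn1, which encodes the vasoconstrictor peptide endothelin 1, was at 29.8 and 2.48 FPKM (-3.15). Dsg3, a desmosomal cadherin of stratified epithelia, was at 11.1 and 0.74 FPKM (-2.80). The other 5 were short non-coding RNAs. Mir680-1 (-2.91) and Snord16a (-2.57) correspond to about 24.2 and 17.0 reads in WT, and Mir1949, Rnu73b and Snord65, at no more than 4.98 reads in WT, were listed at 0 in KO.

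The enteroendocrine list had a median log2 ratio of -0.63, or -0.45 relative to all genes, and lay below all 10000 matched random lists. Of 20 measured members 5 were at least 2-fold lower and 0 higher. Tph1, the enzyme that starts serotonin synthesis in enterochromaffin cells, was at 62.7 FPKM in WT and 15.2 FPKM in KO (-1.98). Gcg, the proglucagon gene of L cells, was at 114 and 30.7 FPKM (-1.86). Nts (neurotensin) had a log2 ratio of -1.28 and Scg2, a granule protein, -1.27. Of the 20 members 15 lay below the median of all genes and 5 above it. The highest, Neurog3, which the naming rule does not select, was at 3.01 and 6.07 FPKM (0.82).

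Cell cycle and DNA replication genes had a median of -0.52, or -0.34 relative to all genes, below all 10000 random lists. Only 2 of 30 were past 2-fold, the replicative helicase subunits Mcm7 (-1.08) and Mcm3 (-1.01), followed by the licensing factor Cdt1 (-0.97) and Mcm5 (-0.92), while 28 of 30 lay below the median of all genes. Cytosolic ribosomal protein genes, which have many pseudogene copies, showed a small shift of the same sign (median -0.38, relative -0.20), with 81 of 81 below the median of all genes and none past 2-fold. Their extremes were Rpl36 (-0.73), Rps27a (-0.63), Rps7 (-0.20) and Rpl4 (-0.19).

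The list of Lgr5+ stem cell markers had a median of -0.31, at percentile 2.92 and so not called, with 4 of 28 members lower and 0 higher. It was called low in 7 of 10 alternative settings, among them the TMM factor, at a percentile of 0.86. The 4 lower members were Cd44, a hyaluronan receptor and Wnt target (85.9 and 28.8 FPKM, -1.54), Scn2b (-1.17), the crypt transcription factor Sox9 (22.5 and 9.68 FPKM, -1.14) and the G1 kinase Cdk6 (-1.0). Lgr5 itself (Entrez gene 14160), the R-spondin receptor that marks these cells, was at 1.79 and 1.88 FPKM. Wnt/beta-catenin targets (median -0.32) were not called, but low with a minimum of 5 FPKM (percentile 0.67) or of 1 FPKM in both libraries (0.74). Cd44, Sox9 and the stem cell regulator Ascl2 (-0.71) were lowest in that list and the Wnt inhibitor Apcdd1 highest (0.55). The reserve stem cell list (-0.36, with Clu at -0.89, Mex3a at -0.68, Cdkn1c at 0.00 and Tert at 0.20) and the Notch list (-0.32, with Dtx4 at -0.96, Notch1 at -0.65, Dll4 at 0.27 and Dll1 at 0.37) were also not called.

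**Figure D2:**
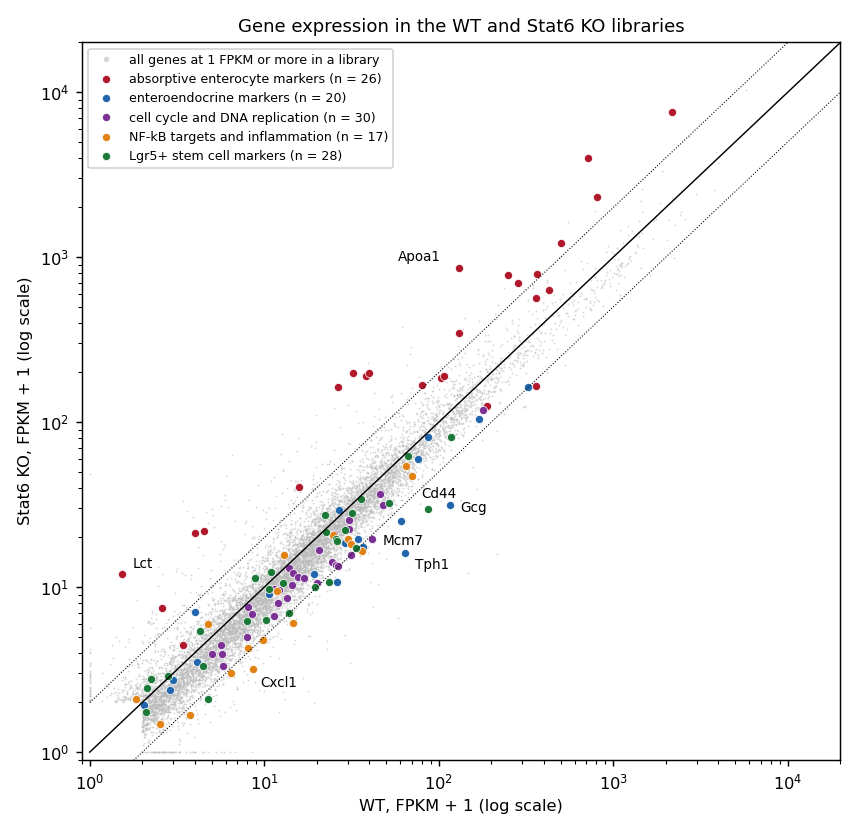
FPKM plus 1 of each gene in the WT library (horizontal axis) against the Stat6 KO library (vertical axis), both on log scales, with grey points for all genes at 1 FPKM or more in a library, coloured points for members of 5 gene lists, a solid line at equal values and dotted lines at 2-fold. Enterocyte markers lie above the upper dotted line for 19 of 26 genes, and enteroendocrine markers lie below the lower one for 5 of 20.

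NF-kB targets and inflammatory genes had the lowest median of the lists fixed in advance (-0.76, or -0.58 relative to all genes), below all 10000 random lists, with 6 of 17 lower and 0 higher. The neutrophil-attracting chemokines Cxcl1 (-1.44) and Cxcl2 (-1.26), the macrophage growth factor Csf1 (-1.17) and the NF-kB subunit gene Nfkb2 (35.1 and 15.5 FPKM, -1.13) were the furthest. Markers of white blood cells (median -0.63, percentile 0.10), of endothelium (-0.62, percentile 0.67) and of nerve and glia (-0.58, percentile 1.51) were low in the same library. Among them were Cd68 (17.7 and 6.08 FPKM), Coro1a, Lyz2 and Fcer1g for white blood cells, with log2 ratios of -1.40, -1.14, -0.89 and -0.85. Endothelial members were Cldn5 (-1.47), Egfl7 (-0.89), Pecam1 (-0.81) and Emcn (-0.73), and neural ones Uchl1 (-0.85), Sox10 (-0.68), Ret (0.00) and Tubb3 (0.44). Several of these were near the minimum level, among them Emcn, Sox10 and Ret at 1.88, 1.28 and 1.15 FPKM in WT. The neural call was lost with the TMM factor, at a percentile of 3.26, the white blood cell call with no minimum level, at 6.18, and the endothelial call with a pseudocount of 5, at 2.64.

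Fetal-like and YAP-responsive genes, which mark regenerating epithelium, had a median of -0.50 with 2 of 20 lower and 0 higher, and only 2 of 10000 random lists lay below it. The annexin Anxa1 (44.2 and 15.1 FPKM, -1.49), the surface protein Ly6a (317 and 157 FPKM, -1.0), the LIM protein Ajuba (-0.89) and the secreted chaperone Clu (-0.89) led it. Immediate early and heat shock genes (median -0.42, percentile 0.05) had 1 of 21 lower, the AP-1 member Fosl1 (16.8 and 4.07 FPKM, -1.81), followed by Hspa1a (-1.0) and Nr4a1 (-0.93), and the differentiation factor Klf4 at 0.93. Basement membrane and integrin genes (median -0.41, percentile 0.47) had 2 of 18 lower, the laminin chain Lama3 (-1.16) and the integrin chain Itgb6 (-1.0), with Col4a1 at -0.76.

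Several stress and metabolic lists were called high in KO at small median shifts. Hypoxia-inducible genes had a median of 0.40, interferon-stimulated genes 0.34 and unfolded protein response genes 0.29, each above all 10000 random lists. The vasodilator peptide gene Adm (0.94) and the collagen hydroxylase Plod2 (0.81) were the highest hypoxia genes, and Slc2a1 (0.05) and Ddit4 (-0.20) the lowest. Of 22 interferon-stimulated genes 1 passed 2-fold, the oligoadenylate synthetase-like gene Oasl2 (10.5 and 29.1 FPKM, 1.39), with Ifit1 at 0.82, Ifih1 at 0.63 and the chemokine Cxcl10 on the other side at -0.90. The endoplasmic reticulum chaperone Hspa5 was at 182 and 336 FPKM (0.88) and Creld2 at 0.91, whereas Phgdh and Slc7a11, of the integrated stress response, were at -0.38 and -0.56.

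NRF2 genes of oxidative stress defence (median 0.28, percentile 99.96) had 3 of 21 higher, the glutathione transferase Gstm1 (784 and 1890 FPKM, 1.27), Osgin1 (1.19) and the epoxide hydrolase Ephx1 (1.18), with Gsta1 at 0.98. The glutathione transferases have close copies and are uncertain. Fatty acid oxidation genes (median 0.18, percentile 99.85) had 2 of 21 higher, the lipid-sensing receptor Ppara (2.01 and 5.65 FPKM, 1.14) and its coactivator Ppargc1a (1.05), with Slc25a20 at 0.80. Glycolysis genes (0.15, percentile 97.86, and 95.73 by the list mean, not called) had none past 2-fold, from Hk1 (0.58) and Gpi1 (0.38) down to Pgam1 and Slc16a3 at 0.04. The BMP pathway (0.18, percentile 99.70) had none past 2-fold, with Bmp2 (0.62) and Smad6 (0.47) highest and Bmp7 (-0.32) and Smad5 (-0.39) lowest.

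Genes that respond to IL-4 and IL-13 through STAT6 were called high rather than low in KO, with a median of 0.29 over 11 measured members and 9993 of 10000 random lists below it. With no minimum level, the median was -0.024 and the list was not called. The only member past 2-fold was the goblet cell gene Clca1 (33.5 and 97.8 FPKM, 1.52), followed by the chemokine Ccl24 (0.97), the kinase Pim1 (0.69) and the lipid-sensing receptor Pparg (0.58). The receptor and signalling list was not called (median -0.13). It held the shared cytokine receptor chain Il2rg (2.81 and 0.67 FPKM, -1.19), Jak3 (-0.52), Irs2 (0.51) and the IL-13 receptor chain Il13ra1 (Entrez gene 16164, 29.6 and 42.8 FPKM, 0.52). The receptor chain shared by IL-4 and IL-13, Il4ra (Entrez gene 16190), was at 14.2 and 13.8 FPKM, and its log2 ratio was -0.04 as deposited and 0.18 with the TMM factor.

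Foxp1 and Ctnnb1 were among the genes named in advance. Foxp1 (Entrez gene 108655), a forkhead transcription factor, was at 8.93 FPKM in WT and 4.95 FPKM in KO. Its log2 ratio of -0.74 was lower than that of all but 4.5% of the 200 genes nearest in mean level, and was -0.54 with the TMM factor. Ctnnb1 (Entrez gene 12387), which encodes beta-catenin, was at 375 and 315 FPKM, with a log2 ratio of -0.25, or -0.02 with the TMM factor. The list of the Foxp1 and beta-catenin axis had a median of -0.25 and was not called, with Gsk3b (0.15) and Tcf7l2 (0.09) highest and Tcf7 (-0.41) and Foxp1 lowest.

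Among the other epithelial lineages, Paneth cell genes had a median of -0.01 with 1 of 18 lower, Pla2g2a (235 and 111 FPKM, -1.08), followed by the defensins Defa3 (-0.87) and Defa26 (-0.78), which have close copies, and Habp2 at 0.69. Goblet cell genes had a median of 0.03 with members on both sides, Clca1 (1.52) and Bcas1 (1.15) at least 2-fold higher and the mucus-folding enzyme Agr2 (245 and 119 FPKM, -1.04) at least 2-fold lower, with Ccl6 at -0.67. Tuft cell genes had a median of -0.13, from Lrmp (0.60) and Alox5ap (0.40) to Hpgds (-0.38) and Avil (-0.63). Pan-epithelial genes had a median of -0.17, from the microvillus protein Vil1 (0.57) and Gata6 (0.55) to Cldn4 (-0.69) and the keratin Krt18 (-0.89). Colon and distal markers (median 0.07) had 3 of 8 higher, the carbonic anhydrase Car4 (2.04), Tmigd1 (2.03) and the chloride exchanger Slc26a3 (1.09), with Saa1 at -0.96. The list was not called, at percentile 96.07, but was called high with a minimum of 5 FPKM (1.09) and by the mean (0.49).

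The remaining lists were not called. Medians were -0.30 for p53 targets, with Phlda3, Gdf15, Psrc1 and Plk2 lowest at -1.03, -1.03, -0.95 and -0.84, and -0.33 for the mesenchymal list, with Tgfbi (1.31) and Loxl2 (0.50) against Vim (-1.19) and Itga5 (-0.70). Apoptosis regulators had a median of -0.14 (Diablo -0.68 and Bcl2 -0.93 lowest) and MHC class II genes -0.02 (Ciita 0.33, H2-Aa 0.16, H2-Eb1 -0.14, H2-DMb2 -0.67). Oxidative phosphorylation genes had a median of -0.02 (Sdhb 0.27, Sdhc 0.24, Cox7a2 -0.35, Ndufa4 -0.44), and cholesterol genes -0.18 (Stard4 0.64 and Insig1 0.46 highest). The histone list, mostly a multigene family, was picked by symbol pattern and may hold genes that are not replication-dependent histones, such as H13 and H1f0. It had a median of -0.16. Its extremes were Hist2h2aa2 (1.41), Hist2h3c2, listed at 0 in WT, and Hist1h4n and Hist2h3c1, listed at 0 in KO. Of the 5 lists without a percentile, stroma had 4 measured members (median -0.49, with Dcn at -1.0, Sparc at -0.67, Thy1 at -0.31 and Tagln at 0.05). Foregut had 2 (Gata4 0.54 and Onecut2 -0.11), and red blood cells 1, Hba-a1, at 0.85 and 1.21 FPKM. The sex list had 1, Xist, at 96.1 and 72.6 FPKM, and the mitochondrially encoded list had none among the genes listed.

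Of the 37 lists with a percentile, 9 were called high and 10 low, where 1.85 calls are expected if members of a list varied independently. Members of a list that vary together can give more calls than that between any 2 cultures, whatever the genotype. For 9 lists, none of them called, the sign of the median changed with the scaling, namely IL-4/IL-13 signalling, tuft, Paneth, MHC class II, pan-epithelial, oxidative phosphorylation, cholesterol, apoptosis and histones.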

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

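Leaving out short non-coding RNAs, and Reg3b and Reg3g from the enterocyte list, were chosen after seeing the data; the other alternatives were planned. Counts of genes are described as close when within 1.5 times, single genes when within 1.5-fold. Values computed from read counts were not run, since the tables hold FPKM only. No paired analysis was possible because there is 1 library per genotype.

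The counts of 295 higher and 263 lower genes depended on the pseudocount, scaling, minimum level and threshold. With a pseudocount of 0.1 the counts were 374 and 604, which turned the majority over to lower genes, and with 5 the counts were 144 and 63. Why the lower count rose more at 0.1 was not tested. The lower count was 171 with the TMM factor, 150 with a minimum of 5 FPKM and 165 with a minimum of 1 FPKM in both libraries. Thresholds of 1.5-fold gave 689 and 1381 genes and 4-fold 51 and 27, by construction. Of the original genes 144 higher and 51 lower were shared by all pseudocounts and scalings. Leaving out short non-coding RNAs gave 255 and 193.

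Of the 19 called lists, 14 kept their call in every alternative run. The nerve and glia list was no longer called with pseudocounts of 0.1 (-0.68) and 5 (-0.21), the TMM factor (-0.39), the median set to 0 (-0.42), no minimum (-0.27) and the mean (-0.39). Without a minimum the STAT6-responsive list (-0.024) and white blood cell list (-0.27) were not called, and the endothelial list (-0.22) was not at a pseudocount of 5, nor glycolysis by the mean (0.19). The cause was not tested. The stem cell list, not called, passed the lower limit in 7 alternatives. The Wnt target, p53, colon, reserve stem cell and histone lists passed a limit in 1 or 2, the colon list at 1.09 with a minimum of 5 FPKM. Enterocyte medians kept their call throughout, also without Reg3b and Reg3g (1.52). These are the 2 lowest members of that list, so leaving them out could not lower its median and is no check of it. Of 177 other named genes 20 moved past 1.5-fold with a pseudocount of 0.1 and 33 with 5, none with another scaling. No named gene past 2-fold changed sign. The largest scaling shift was -0.23 on the log2 scale, too small for either, and a pseudocount cannot change a sign. The results for scaling and for sign were therefore fixed in advance. Depth limits low genes most, and without replicates the spread between cultures is unknown.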

Other observations

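Of the tests below, those of genes of like length and GC content, of the enterocyte share, of non-epithelial cells and of an unedited library were chosen after the results were seen, as were the gene lists and families described below that the results section does not hold.

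Genes of xenobiotic metabolism under the nuclear receptors CAR and PXR stood higher in KO, with 16 of 22 at least 2-fold higher and a median log2 ratio of 1.80. Over the 17 that neither a list fixed in advance nor the 12 highest genes held, the median was 1.59. These 17 were chosen in the same step, after the results were seen, so their median is no separate support. The same holds for the remaining members of the other lists chosen then. Nr1i3, which encodes CAR, was at 2.07 and 8.19 FPKM, the aldehyde dehydrogenase Aldh1a1 at 68.03 and 283.6 FPKM, and the carboxylesterase Ces2a, of a multigene family, at 60.6 and 373.7 FPKM. Carriers of sugars and amino acids were at least 2-fold higher in 8 of 11 members, and in 5 of the 8 that no list fixed in advance held. They included the glucose carrier Slc5a1 (38.9 and 196.7 FPKM), the fructose carrier Slc2a5 (1.46 and 12.2 FPKM) and the neutral amino acid carrier Slc6a19 (4.94 and 32.9 FPKM). Genes of the villus base had a median of 0.80, with 2 of 7 higher and 1 lower, Reg3g. Genes of the villus tip had a median of 0.40 (percentile 99.75), with 1 of 9 higher, the apolipoprotein Apoa4 (1.64), and 0 lower. Klf4, Apob, Krt20 and Creb3l3 were at 0.93, 0.83, 0.65 and 0.40, and Slc28a2, Ada, Egfr and Neat1 at -0.21, -0.63, -0.69 and -0.77. Over the 5 tip genes that no list fixed in advance held, the median was -0.63 with 0 higher, so the positive median rests on genes already counted. Across 234 measured solute carrier genes, 34 were higher and 2 lower.

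On the other side, genes of squamous epithelium had a median log2 ratio of -1.30, with 5 of 9 at least 2-fold lower. Without Dsg3, one of the 12 lowest genes, the median was -0.82 and 4 of 8 were lower. They included the serpin Serpinb5 (43.7 and 9.51 FPKM), the epithelial cell cycle regulator Sfn (302 and 122 FPKM) and Krt6a (4.25 and 1.04 FPKM), while Ly6d was at 0.58. MAPK-responsive genes were lower in 4 of 15, and in 2 of the 11 that neither a list fixed in advance nor the 12 lowest genes held. These were the EGF receptor ligand Hbegf (40.1 and 12.9 FPKM) and Etv4 (13.6 and 6.10 FPKM), and Dusp6 was at 0.63. Chemokine genes were lower in 5 of 19 and higher in 0, with Ccl2 at 21.7 and 3.21 FPKM. The WT library already held high levels of differentiation genes, with Fabp1 at 2173 FPKM and Krt20 at 361 FPKM, beside Lgr5 at 1.79 and Olfm4 at 6.92 FPKM. Its most abundant gene was Sprr2a3, of a family of near-identical copies, at 5782 FPKM, against 10307 FPKM in KO. Sprr2a3 (0.83) was outside the squamous list, which held the related Sprr2f (-2.28). The low median of that list therefore does not extend to all genes of this family.

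The 3 other scalings took log2 shifts of -0.23, -0.19 and -0.04 off KO, which could only raise the enterocyte median, to at least 1.49. They were therefore no test of scaling as the cause. A scaling moves all genes nearly alike, while the list stood 1.64 above the median of all genes, which argues against scaling as the cause. Other genes in the same of 10 length and 10 GC bins had a median of -0.16 (-0.27 to -0.06 by bin), far below the list's 1.46, and removing both trends, which moved genes little, left the list 1.64 above all genes, as before, so length and GC content do not account for it. A larger share of enterocytes, as the only difference, would lower the other lineages alike. In these 2 libraries the enteroendocrine median lay -0.64 from that of Paneth and goblet genes (95% bootstrap interval over genes -0.97 to -0.14). This contrast was chosen after the list medians were seen, and the interval does not cover the spread between cultures. The contrast therefore describes these 2 libraries and does not decide on the share of enterocytes. A difference between the cultures in density, passage or day of harvest cannot be told apart from genotype with 1 library per genotype. An effect of genotype stays open as well and was not tested.

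The lower NF-kB and inflammatory genes lay beside lower markers of other cell types. Over 26 white blood cell, endothelial and stromal markers, none of them in another list, the median log2 ratio was -0.45 relative to all genes. These markers together lost 45.1 FPKM and the NF-kB list 108 FPKM, and the most abundant of them, Cd68, was at 17.7 FPKM in WT. Fewer non-epithelial cells in the KO culture could contribute, and cannot be told apart from lower expression in the epithelium, because no library of pure epithelium was compared and how many of these markers the epithelium also expresses was not measured. A role of genotype was not tested separately.

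The Stat6 transcript was not lower in the KO library. Its log2 ratio was 0.10, and the genes that respond to STAT6 lay at percentile 99.93, not low. An unedited or mislabelled library and an edited one with a stable transcript cannot be told apart, since gene-level FPKM does not show small insertions or deletions. The labels list no IL-4 or IL-13 in the medium, so STAT6-responsive genes may carry little signal in either culture.

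Dbp, a transcription factor with a strong daily rhythm, was at 1.45 FPKM in WT and 9.16 FPKM in KO. A candidate explanation is a different circadian phase at harvest. The 8 genes that peak with Dbp had a median 0.82 above that of all genes, as a shift of phase predicts, with Usp2 at 1.65 and Tef at 1.18. The 6 antiphase genes did not lie below it as predicted (0.20 above), with Arntl at -0.40 and Npas2 at -0.47. The phase therefore stays open.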
